A study of Hordeum vulgare with 18 samples.

How the data were processed

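The series is a time course of drying in barley seedlings. Per the labels, 7 seeds of the cultivar Haruna Nijo germinated in water on filter paper for 4 days at 24 °C with an 8 h day, and 3 germinated seeds were then moved to dry paper at 23 °C for the stated hours before shoot and root were harvested separately. Per the labels' protocols, total RNA was extracted with Trizol, and 400 ng was labelled with an Agilent Quick Amp kit, untreated 0 h RNA with Cy3 and dried RNA with Cy5 on each array. No array has the dyes swapped. A gene-specific dye bias therefore cannot be told from drying in the comparisons with untreated. It cancels in the differences between times and between tissues only as far as it does not change with the signal. Groups came from the tissue and time in the labels, with 4 biological replicates at 3 h and 6 h. At 24 h replicate 1 was used and the others were not analysed here. For the transfer after germination, the growth protocol speaks of filter papers for the 6 arrays of replicate 1 and of paper towels for the 12 others, while the treatment protocol names paper towels for all.

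The deposited scanner files hold spot intensities, and per the submitters' processing notes they were made with Agilent Feature Extraction 9.1. The file headers name version 9.1.3.1 for the 2 arrays of replicate 1 at 6 h and 9.5.3.1 for the 16 others. The deposited files also carry a log10 ratio of red over green per spot, and the authors' series table holds that same log10 ratio on every array (largest difference 0, medians near 0). From the deposited intensities, mean signals were corrected with the median local background by normexp with an offset of 50, and each array was normalized by loess, with the 1417 control spots of 43900 and outlier-flagged spots at weight 0. Outlier-flagged spots were left out of the fits. The log2 ratios computed here are Cy5 over Cy3. No normalization between arrays was used for ratios, and Cy3 levels were taken after Aquantile. Probes well above background in at least 1 channel on at least 4 of the 16 arrays were kept, 39471 of 42483, and 3012 were left out. The spots saturated in the red channel reached 18 on 1 array (shoot at 24 h). They were kept.

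Tests used limma 3.58.1 in R 4.3.3. A model with the 4 group means over the 16 arrays gave 12 residual degrees of freedom and a prior of 2.40. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change, two-sided. Differences between times and tissues were contrasts of the same model, and untreated root and shoot were compared on Cy3 signals averaged by tissue and replicate, 4 against 4. At 24 h values are given without a test, and a fit that takes the lone array to vary like the others was tried as an alternative. Where a channel was not well above background on any array of a group, the fold is a lower bound, taken from the bright group's mean against the higher of the array's lowest signal well above background and the probe's own signal, per channel after loess and Aquantile, and open to dye bias.

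The scanner files name probes by identifier and sequence only. None of the 42483 probe identifiers matched the reference table of the MorexV3 assembly, and 0 of the 33 gene lists fixed beforehand had members. Named probes follow a rule fixed before the data were examined for the case of no gene names: at most 2 that rose and 2 that fell in a comparison, those with the largest change among called probes with the same sign in all 4 replicates, with the brightest probe standing for a clone name. The 42483 probes carry 36632 clone names, and 5851 of these have 2 probes. Among the 5748 such pairs in the tests, the log ratios correlated at 0.990 to 0.995 in each comparison with untreated, and 1 pair with both probes called in shoot at 3 h went in opposite directions, so counts of probes exceed counts of clones (8911 probes and 7375 clone names in shoot at 3 h).

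Replicate numbers pair the samples. Deviations of log ratios from the group means correlated between 0.503 and 0.884 for the 8 pairs of same-numbered arrays of a tissue, and between 0.138 and 0.473 for the 16 pairs across tissues. Replicates 2, 3 and 4 each lay on a slide of their own that held all 4 groups, and replicate 1 was spread over 3 slides, each with shoot and root of 1 time. For replicates 2, 3 and 4 the number and the slide therefore cannot be told apart. In replicate 1 the pairs of log ratios within a tissue lay on different slides and correlated at 0.558 in shoot and 0.503 in root, the lowest of the 8. The Cy3 deviations of same-numbered arrays of a tissue correlated at 0.910 to 0.967 and the Cy5 deviations at 0.274 to 0.728.

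The fit was tested on simulated log ratios for 39471 probes with known changes in 200. For shoot at 3 h against untreated, 94.0% of 50 probes changed by 1.5 on the log2 scale were called, with 2 false calls. For the difference between root and shoot at 3 h the share was 82.0%, with 9 false calls. Alternatives were no background correction, the scanner's processed signals, median centring, scaling or Aquantile between arrays, the series table, other filters, other thresholds, separate fits, the replicate number or the slide as a block, and leaving out each replicate. Other alternatives were added after seeing the data: a replicate block within each tissue, and counts over probes above background in both groups. The tests of gene lists could not be run.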

Results

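Gene expression was measured in the shoot and the root of germinated barley (Hordeum vulgare, cultivar Haruna Nijo) after 3, 6 or 24 h of drying on paper towels, on 2-colour 60-mer oligonucleotide microarrays. Each of the 18 arrays set RNA of a dried sample, labelled with Cy5, against RNA of untreated tissue of the same kind taken at 0 h, labelled with Cy3. Shoot and root at 3 h and at 6 h had 4 biological replicates each, and each tissue had 1 array at 24 h, from replicate 1. The values below are log2 ratios of dried over untreated signal, so a value of 1 is a 2-fold rise. Of 42483 probes, 39471 were well above background in at least 1 channel on at least 4 of the 16 arrays at 3 h and 6 h and were tested. Between 86.1% and 89.1% of the features on an array were well above background in the untreated channel, and between 86.4% and 90.2% in the dried channel. The number of arrays limits the precision of every value. The files give no gene names for the probes, so probes are named by their identifiers, at most 2 that rose and 2 that fell in a comparison. The untreated samples were all taken at 0 h, so the ratios hold the effects of drying, of the transfer and of elapsed time together.

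In the shoot, drying for 3 h changed a large part of the measured transcripts. A total of 4808 probes rose and 4103 fell (limma, adjusted p under 0.05 and at least 2-fold, n = 4), which is 22.6% of the probes tested. With the values of the deposited series table the balance turned round, to 5667 that rose and 6448 that fell. Scaling between arrays, which makes all arrays equally spread, left 2735 that rose and 1939 that fell. Rises reached further than falls: 1713 probes rose at least 4-fold and 756 fell at least 4-fold. The probe with the largest rise among those changed the same way in all 4 replicates, Hv3139H19_2, rose by 8.43 ± 0.63 on the log2 scale (SD, n = 4), 346-fold, with an adjusted p of 1.04e-06 in limma. Hv3095J24_1 rose by 8.22 ± 0.61 (SD, n = 4; limma adjusted p 5.36e-07). Among the probes that fell, Hv2001A05_1 stood at a log2 ratio of -5.34 ± 0.56 (SD, n = 4; limma adjusted p 9.79e-09), and its dried channel was well above background on 3 of the 4 arrays. Hv3129K10_1 stood at -4.98 ± 0.57 (SD, n = 4; limma adjusted p 3.26e-09). Of the 8911 probes called, 8823 had the same sign in all 4 replicates.

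After 6 h of drying the shoot showed 4857 probes that rose and 5540 that fell (limma, n = 4), 26.3% of those tested. Falls were no longer the majority with median centring in place of loess (5809 rose and 5002 fell) or by the adjusted p without the fold minimum (13941 and 12482). The number of probes that fell at least 4-fold was 1557, and 1829 rose at least 4-fold. Hv2146A12_1 rose by 8.63 ± 0.22 on the log2 scale (SD, n = 4), 395-fold, with an adjusted p of 3.05e-07 in limma. Its probe sequence is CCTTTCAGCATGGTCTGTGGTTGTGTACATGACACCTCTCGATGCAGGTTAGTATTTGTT. Hv3139H19_2 rose by 8.53 ± 0.11 at this time (SD, n = 4; limma adjusted p 7.19e-07), and its probe sequence is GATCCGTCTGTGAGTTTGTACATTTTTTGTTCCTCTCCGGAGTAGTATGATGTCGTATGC. The probes with the largest falls were Hv3007F02_1, at -6.26 ± 0.47 (SD, n = 4; limma adjusted p 7.99e-11), and Hv1096O19_1, at -6.17 ± 0.48 (SD, n = 4; limma adjusted p 4.74e-09). The sequence of Hv3007F02_1 is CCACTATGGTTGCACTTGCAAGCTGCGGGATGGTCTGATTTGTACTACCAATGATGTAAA. The 2 shoot times shared 3949 probes that rose at both and 3400 that fell at both, and no probe was called in opposite directions. Independent lists of these lengths would share 592 rises and 576 falls. In a simulation with no drying effect and same-numbered samples correlated as observed, no probe was called at both times, which its setting largely fixed in advance. Across probes, which are not independent replicates, the mean log ratios at 3 h and 6 h had a correlation of 0.923. The 0.698 of that simulation restates the correlation put into it (0.695, the median of same-numbered arrays of a tissue). The correlation averaged 0.874 when the 3 h values came from 2 replicates and the 6 h values from the other 2. The covariance was 1.196, against 0.0300 in the simulation.

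**Figure D1:**
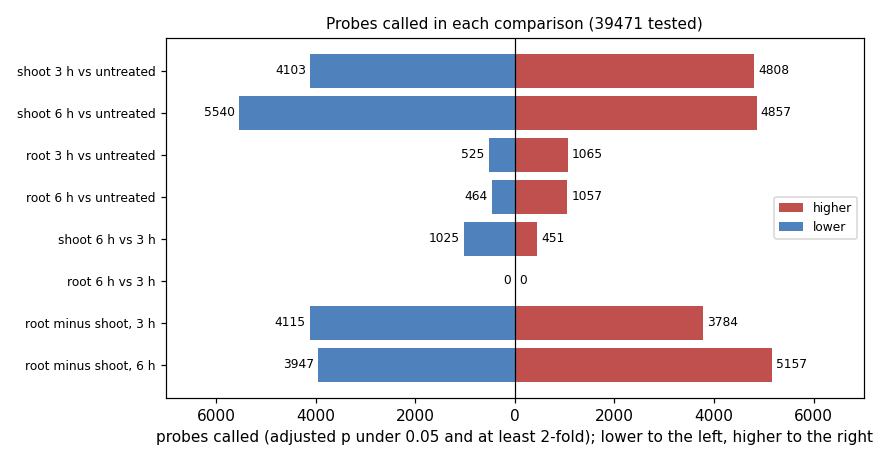
Number of probes called in each comparison (adjusted p under 0.05 and at least 2-fold), with probes higher in the first-named group or condition to the right and lower ones to the left. The shoot bars at 3 h (4808 and 4103) are several times as long as the root bars (1065 and 525), and root at 6 h against 3 h has no bar.

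In the root, drying for 3 h gave 1065 probes that rose and 525 that fell (limma, n = 4), 4.03% of those tested. Hv2012A11_1 rose by 5.92 ± 1.29 on the log2 scale (SD, n = 4; limma adjusted p 2.68e-07). Hv2056I16_1 rose by 5.61 ± 0.31 (SD, n = 4; limma adjusted p 5.66e-09), with its untreated channel well above background on 3 of the 4 arrays. Hv2023E18_1 stood at -4.59 ± 1.51 (SD, n = 4; limma adjusted p 0.000275) and Hv2016I02_1 at -4.05 ± 1.09 (SD, n = 4; limma adjusted p 7.93e-05). In replicates 1 to 4 they stood at -3.64, -5.83, -5.92 and -2.97, and at -3.61, -4.84, -5.05 and -2.72. The end of the Hv2016I02_1 sequence is the start of the Hv2023E18_1 sequence, so both may read the same transcript, which was not tested. Across probes, pairs of root arrays at 3 h correlated at 0.435 to 0.802 and pairs of shoot arrays at 0.824 to 0.929. Such a correlation also falls when the changes are smaller, so it does not by itself show a wider spread between root replicates. The SD of the log ratios on an array averaged 0.652 in root and 1.14 in shoot at 3 h. Fitting the 4 root arrays at 3 h on their own called 953 probes in place of 1590. The share of rises among the called probes, 67.0%, was 56.7% with the scanner's processed signals and 54.5% with the values of the deposited series table.

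After 6 h the root showed 1057 probes that rose and 464 that fell (limma, n = 4). Hv2146A12_1, the probe with the largest rise in the shoot at this time, also had the largest rise in the root, at 6.36 ± 2.09 on the log2 scale (SD, n = 4; limma adjusted p 0.000163), with values between 3.36 and 7.85. The SE behind that p-value, 0.83, was pooled over both tissues, and the SD of this probe in shoot at 6 h was 0.22. Hv3007E07_1 rose by 6.22 ± 1.60 (SD, n = 4; limma adjusted p 8.34e-05). Hv2022I18_1 stood at -4.25 ± 1.94 (SD, n = 4; limma adjusted p 0.000505) and Hv2023E18_1 at -4.20 ± 2.35 (SD, n = 4; limma adjusted p 0.00054). The fall of Hv2023E18_1 was no longer called when the root arrays at 6 h were fitted on their own (limma adjusted p 0.0618, and 0.000178 to 0.0618 over its alternatives). Both root times shared 871 probes that rose and 397 that fell, where independent lists would share 28.5 and 6.17, and none was called in opposite directions. Across probes the 2 times correlated at 0.961, and at 0.748 on average between disjoint pairs of replicates. The 0.696 of the simulation without effects again restates the correlation put into it. The covariance was 0.277, against 0.0301 in the simulation. The share of rises, 69.5%, was 56.1% with the values of the deposited series table, where 1501 probes rose and 1176 fell.

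Between 3 h and 6 h the shoot values changed further. Relative to 3 h, 451 probes were higher and 1025 lower at 6 h (limma contrast, adjusted p under 0.05 and at least 2-fold, n = 4 per time). Hv2085F21_2 was 3.11 higher at 6 h on the log2 scale (SE 0.56, limma adjusted p 0.0023): its ratio to untreated was 0.39 ± 0.79 at 3 h and 3.51 ± 1.09 at 6 h (SD, n = 4). Its call was lost with scaling between arrays (2.00, limma adjusted p 0.161) and in the limma test against a 2-fold change (limma adjusted p 0.493), over a range of 0.000149 to 0.493 in its alternatives. Hv2140P21_1 was 2.71 higher (SE 0.56, limma adjusted p 0.00534), with the untreated channel well above background on 1 array at 3 h and 2 at 6 h, and its limma adjusted p was 0.0817 without replicate 2 and 0.0703 without replicate 3, over a range of 0.00147 to 1 in its alternatives. Hv1081E20_1 differed by -3.24 (SE 0.34, limma adjusted p 7.98e-05), from -2.10 ± 0.66 at 3 h to -5.34 ± 0.77 at 6 h (SD, n = 4), and Hv2109P06_1 by -3.20 (SE 0.33, limma adjusted p 6.94e-05). Of the probes that had fallen by 3 h, 329 fell further and 138 were higher at 6 h than at 3 h. Of those that had risen by 3 h, 81 rose further and 62 were lower at 6 h. A further 571 probes that were not called at 3 h had fallen by 6 h with a called difference, and 83 had risen. The count of 1476 depended on single replicates: it was 982 without replicate 2 and 900 without replicate 3. It was 133 with scaling between arrays and 21 in the limma test against a 2-fold change, all 21 lower at 6 h. The share of higher probes, 30.6%, was 41.8% with median centring in place of loess and 52.1% with the values of the deposited series table. On the slides that held both times, each with 1 array per time, 4.62% to 9.31% of the measured probes differed at least 2-fold.

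In the root no probe was called between 3 h and 6 h (limma, 0 probes at an adjusted p under 0.05, with or without the replicate number as a block). At an unadjusted p under 0.05 there were 175 probes of 39471, 513 with the replicate number as a block and 1304 with a block within each tissue, an alternative chosen after seeing the data. With no effect and independent arrays, a share of 0.05 of the probes would have such a p. All these counts lie below that share, so the tests were conservative, most of all the fit that leaves out the pairing. On simulated data of this design, changes of 1.5 on the log2 scale in 50 probes were called for 76.0% of them without the block and 82.0% with it. On the slides that held both times, each with 1 array per time, 0.733% to 1.83% of the measured probes differed at least 2-fold.

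**Figure D2:**
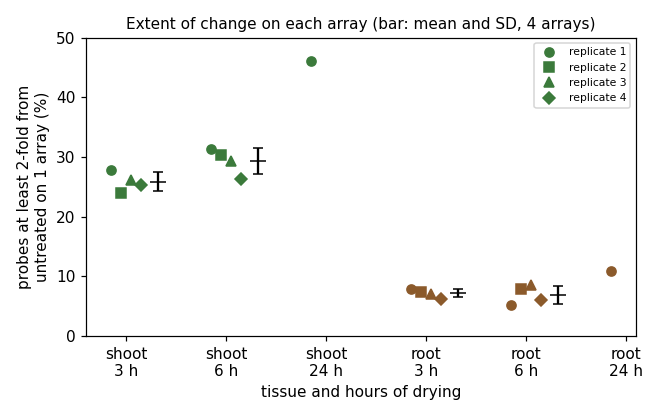
Percentage of probes, among those well above background in both channels, whose signal was at least 2-fold from untreated on each array, by tissue and hours of drying. Each symbol is 1 array and each bar the mean and SD of 4 arrays, and no shoot array (24.0% and up) overlaps a root array at 3 h or 6 h (8.54% and down).

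The response of shoot and root differed for many probes, by a test of the difference itself. At 3 h, 7899 probes responded differently (limma contrast, n = 4 per tissue): 3784 had a higher log ratio in root and 4115 a higher one in shoot, a balance that turned round with the values of the deposited series table (5464 and 4963) and with scaling between arrays (2389 and 2165). At 6 h there were 9104 such probes, 5157 higher in root and 3947 higher in shoot, against 4345 and 4366 with median centring and 9934 and 10658 by the adjusted p without the fold minimum. In 7322 of the probes at 3 h and 8689 at 6 h, the shoot had the larger absolute change. Hv3018N10_1 differed most at both times. Its log ratio was 6.62 ± 1.17 in shoot and -1.76 ± 1.04 in root at 3 h, and 7.12 ± 1.07 and -0.72 ± 0.67 at 6 h (SD, n = 4), a difference of -8.38 (SE 0.65, limma adjusted p 2.32e-07) and -7.83 (SE 0.65, limma adjusted p 2.82e-07). Its dried root channel was well above background on 2 of the 4 arrays at each time. Hv2121K13_1 likewise rose in shoot, to 6.22 ± 1.42 at 3 h (SD, n = 4), and stood at -0.72 ± 0.79 in root (difference -6.93, SE 0.70, limma adjusted p 2.33e-06). In the other direction, Hv3129K10_1 fell in shoot at 3 h and stood at -0.58 ± 0.65 in root (SD, n = 4; difference 4.40, SE 0.42, limma adjusted p 1.55e-06). For Hv3007F02_1 at 6 h the dried root channel was not well above background on any of the 4 arrays, so its root ratio was not measured and no difference is given. For Hv1045E17_1 at 3 h and Hv2050O22_1 at 6 h neither root channel was well above background on any array, so no root value was measured and no difference is given. The same held for 1 of the tissues in 210 of the called probes at 3 h and 334 at 6 h. At both times shoot and root of a replicate lay on the same slide. Within each of these slides, with 1 array per tissue, 23.6% to 25.3% of the measured probes differed at least 2-fold at 3 h and 23.9% to 28.8% at 6 h.

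Probes that changed in both tissues mostly changed the same way. At 3 h, 805 probes rose in both, 160 fell in both and 34 went in opposite directions, where independent lists would give 130, 54.6 and 175. At 6 h, 817 rose in both, 284 fell in both and 44 were opposite, against 130, 65.1 and 205. In the simulation without effects no probe was called in both tissues, which its setting largely fixed in advance. Of the 805 shared rises at 3 h, 403 were larger in shoot and 11 larger in root by the test of the difference, and 391 had no called difference. The 403 had a median log ratio of 4.15 in shoot and 1.88 in root. Of the 817 shared rises at 6 h, 354 were larger in shoot and 11 larger in root. Across probes the mean log ratios of the 2 tissues correlated at 0.498 at both times. The simulation gave 0.294 at 3 h and 0.290 at 6 h, which restate the correlation put into it. The covariances were 0.289 and 0.320, against 0.0129 and 0.0124 in the simulation. Hv2056I16_1 stood at 4.46 ± 0.39 in shoot and 5.61 ± 0.31 in root at 3 h (SD, n = 4). Hv2146A12_1 stood at 7.96 ± 0.37 in shoot and 5.35 ± 2.91 in root at 3 h (SD, n = 4).

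**Figure D3:**
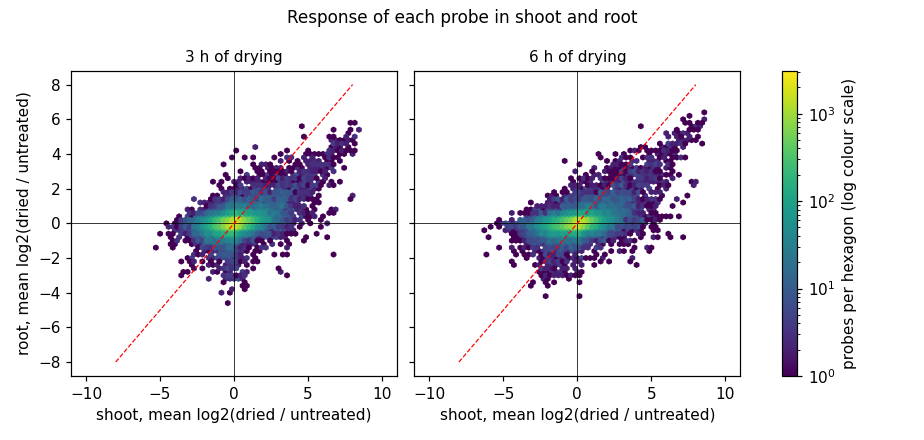
Mean log2 ratio of dried over untreated signal of each tested probe in shoot (horizontal) and root (vertical) after 3 h and 6 h of drying, as hexagons coloured by the number of probes on a log scale, with a dashed red line of equal response. Most hexagons spread along the horizontal axis, and the probes that rise in both tissues lie mainly below the line (403 of the 805 shared rises at 3 h were larger in shoot and 11 larger in root).

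Untreated root and untreated shoot differed in 14990 probes (limma on Cy3 signals, arrays of a tissue and replicate averaged, n = 4 per tissue). Of these, 8013 were higher in root and 6977 higher in shoot. Differences of at least 8-fold numbered 2883 towards shoot and 1218 towards root. Hv2088P23_1 was higher in root by 10.35 (SE 0.27, limma adjusted p 5.48e-09) and was well above background on 7 of the 9 shoot arrays. Hv2022H16_1 was not well above background in shoot on any array and was at least 934-fold higher in root (limma adjusted p 5.56e-09). Hv1089J16_2 and Hv1027M07_2 were higher in shoot in all 4 replicates, each with a fitted log2 value of -10.60 for root relative to shoot (limma adjusted p 2.13e-08 and 3.72e-09). Both were well above background on 9 shoot arrays and on 3 and 4 of the 9 root arrays, so the size of these differences was not measured precisely. In dried shoot at 6 h, 3665 of the 6977 probes that were higher in untreated shoot fell and 413 rose, while 499 of the 8013 that were higher in untreated root fell and 1648 rose.

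At 24 h each tissue had 1 array, so its values have no replicate check and are given without a test. On the shoot array 16672 probes were at least 2-fold from untreated, 8085 up and 8587 down (9134 and 8922 with the scanner's processed signals), which is 46.1% of the probes well above background in both channels. The shoot arrays of the same replicate had 27.8% at 3 h and 31.4% at 6 h. In replicate 1 each time lay on a slide and in a scan of its own, so time, slide and scan cannot be told apart in this paragraph. On the root array 3945 probes were at least 2-fold from untreated, 10.8% of those above background, against 7.81% at 3 h and 5.25% at 6 h. Probes called from replicates 2 to 4 alone were followed in replicate 1. The 4500 probes that rose in shoot at 6 h in those replicates had medians of 1.85, 1.93 and 2.35 at 3, 6 and 24 h, and 90.7% of them were at least 2-fold up at 24 h. The 5605 that fell had medians of -1.16, -1.58 and -2.21. In root the 1110 probes that rose had medians of 1.97, 1.45 and 1.76, and the 690 that fell had -1.19, -0.75 and -1.80. In shoot, 5503 probes were at least 2-fold from untreated at 24 h and under 2-fold at both 3 h and 6 h, and 1598 in root, among probes well above background on all 3 arrays of replicate 1. Hv2083E12_1 had the highest ratio on the shoot array, 8.61, with 9.03 at 3 h and 9.65 at 6 h in the same replicate. Hv2045I20_1 stood at -7.70 on the shoot array at 24 h, with -4.19 at 3 h and -3.63 at 6 h. In root Hv3079F06_2 stood at 7.79 and Hv2067O17_1 at -6.94, the latter with 0.41 at 3 h and -0.40 at 6 h.

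**Figure D4:**
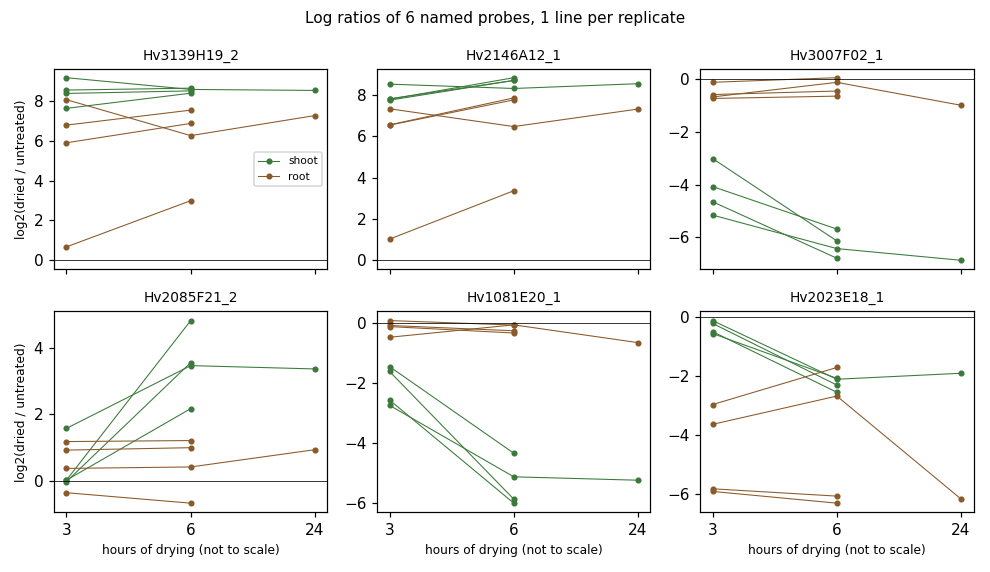
Log2 ratio of dried over untreated signal of 6 of the named probes against hours of drying (axis not to scale), with shoot in green and root in brown and 1 line per replicate, the 24 h point being replicate 1 alone. Hv3139H19_2 lies between 7.63 and 9.17 in shoot, Hv3007F02_1 falls from -4.23 at 3 h to -6.26 at 6 h in shoot, and the root lines of Hv2146A12_1 lie between 3.36 and 7.85 at 6 h.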

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

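The tests on the extent of change in shoot and root, on dye bias, on samples of the same number, on other splits of the samples and on gaps between replicates were chosen or set out only after the results were seen. The tests on independent replicates of baseline and response were set out before their results were seen.

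Shoot and root responded differently in 7899 probes at 3 h and 9104 at 6 h, and shoot at 6 h differed from shoot at 3 h in 1476. Each is a tested difference between groups. The 8 arrays of each comparison were split in 35 ways into 4 and 4. Splits other than the real one gave at most 1 probe at 3 h and 42 at 6 h for the tissue difference, and at most 728 for the shoot times. For untreated root against shoot, the 8 untreated samples averaged by tissue and replicate were split, with at most 0 (real value 14990). Only the real split reached the real count in each, 1 of 35. Were the arrays exchangeable, this share would lie under 0.05 in each of these 4 comparisons. The replicate numbers pair the samples, however, so the arrays are not exchangeable and these splits do not exclude chance. Only 8 of the splits part every same-numbered pair, too few for a share under 0.05. Among these the highest other count was 1 for the tissue difference at 3 h, 42 at 6 h, 1 for the shoot times and 0 for the untreated tissues. For root at 6 h against 3 h the real count was 0, and all 35 splits gave as many. The highest, 1111, put both times of replicates 1 and 4 against both times of replicates 2 and 3, and the highest in shoot, 728, was the same division. Such a split sets 2 replicate numbers against 2 but counts them as 4 against 4, in a fit without the pairing. Same-numbered arrays are also alike across tissues, so the 2 tissues are not independent evidence of a structure among replicates. With the replicate number as a block, 1742 probes were called in shoot and 0 in root. For the comparisons with untreated, turning the signs of arrays gives 8 splits, too few for a share under 0.05. Of these only the real one, 1 of 8, gave its count: 8911 against at most 0 in shoot at 3 h, 10397 against 179 at 6 h, 1590 against 103 in root at 3 h and 1521 against 23 at 6 h.

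More probes changed in dried shoot than in dried root. Compressed ratios on the root arrays are argued against by control features named r60, whose log10 ratios span as much on root arrays as on shoot arrays (ratio of mean spans 1.01). The span does not test the centre of the ratios. The median log10 ratio of these features was 0.90 in shoot and 0.93 in root for replicate 1 at 3 h. On the other arrays at 3 h and 6 h it lay between -0.07 and 0.37. Whether this bears on the balance of rises and falls was not tested. A wider spread between root replicates as the whole cause is argued against by single arrays, where the lowest shoot array had 2.81 times the percentage of 2-fold probes of the highest root array at 3 h or 6 h. At 3 h root replicates did spread more for some named probes (Hv3139H19_2, SD 3.25 in root and 0.63 in shoot) and less for others (Hv2056I16_1, 0.31 and 0.39). The normalization is argued against by 4 others, under which shoot had at least 4.63 times the called probes of root (scaling the arrays to equal spread, which imposes equality, gave 4674 and 3364 at 3 h). A difference between the tissues in how they respond or in how fast they dry stays open as a hypothesis, since water content was not measured here.

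Probes that changed the same way in both tissues could reflect dye bias, since no array has the dyes swapped. A dye bias that does not change with the signal gives, as the whole cause, the same ratio in both tissues. Such a bias is argued against for the 430 such probes at 3 h and 436 at 6 h whose tissues differed by a called difference. Probes were not matched on signal between the tissues, so a bias that changes with the signal was not tested. For the other 535 and 665 probes dye bias and drying cannot be told apart, because the dyes were never exchanged. Chance values shared by samples of the same number are argued against: with shoot and root taken from different numbers, the covariance kept 0.946 of its value at 3 h and 0.952 at 6 h. A response common to both tissues stays open as a hypothesis.

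Probes higher in untreated shoot than in untreated root tended to fall in dried shoot. An untreated measurement that enters both sides is argued against by independent replicates: with bias from 2 replicates and response from the others, shoot-biased probes stood lower than root-biased ones by a median log ratio of -0.63 ± 0.23 at 3 h and -1.29 ± 0.09 at 6 h (SD, n = 4 replicates, all 4 below 0). More room to fall in bright probes is argued against by comparing among probes of like untreated shoot signal, where the differences were -0.66 ± 0.28 and -1.35 ± 0.13. A loss of shoot-specific expression on drying is a hypothesis that these values are consistent with, and elapsed time since 0 h stays open beside it.

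A control feature on the array named CAB_QC, outside the measured probes, gave signal in shoot. Its untreated-channel mean signal was at least 132 on every shoot array and at most 85.1 on every root array. In dried shoot at 6 h its mean signal was 204, 91.1, 76.9 and 89.5 in replicates 1 to 4, over backgrounds of 47 to 58.3. The size of its ratio there was thus not measured precisely. The log2 ratio of this feature came from the scanner's log10 ratio, not from the loess values used elsewhere. It was -0.38 ± 0.47 in shoot at 3 h and -2.04 ± 0.19 at 6 h (SD, n = 4), lower at 6 h in 4 of 4 replicates (exact permutation test over 16 sign assignments of the 4 paired differences, two-sided, p = 0.125, the smallest that 4 pairs allow). On the shoot array at 24 h, from replicate 1, it was -1.45, higher than the -2.26 of that replicate at 6 h.

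A gap test was applied to 145 sets of 4 measured replicate values: measures of signal and spread per array, the control feature, differences within replicates and the named probes. It marked a sample far from the others in 12 sets, where chance alone marks about 1 in 20, and 10 of the 12 were in replicate 1 and 2 in replicate 3. In replicate 1 the median untreated signal in shoot at 6 h was 904, spots marked as outliers by the scanner numbered 457 in shoot and 503 in root at 6 h, and the untreated signal of CAB_QC in shoot was 377 at 3 h and 368 at 6 h. Of the named probes in replicate 1, Hv2001A05_1 stood at -3.50 in shoot at 6 h, Hv2056I16_1 at 4.50 and Hv2140P21_1 at 0.51 in root at 6 h, and Hv2085F21_2 at 1.58 and Hv2146A12_1 at 8.51 in shoot at 3 h. In root replicate 3, Hv2146A12_1 stood at 1.02 and Hv3007E07_1 at 1.35 at 3 h. The 457 and 503 marked spots fell on the only 2 arrays read with version 9.1.3.1, which shared a slide. The 16 arrays read with version 9.5.3.1 had 2 to 16 marked spots, those of replicate 1 at 3 h and 24 h among them. These 2 counts therefore go with the extraction version or the slide, which cannot be told apart, and not with replicate 1 as a whole. No explanation was tested for the other marked values.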

How the results depend on the processing

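The alternatives were listed before the data were examined, except the block within each tissue and the counts over probes above background in both groups. Of 154 alternative values of the counts, 123 stayed within 1.5 times. Of 508 values for 25 named probes in 32 pairs of probe and comparison, 500 kept their direction and their call, 8 kept the direction without the call, and 0 reversed. Part of this agreement was fixed in advance. Both totals hold the Aquantile values, the counts hold root at 6 h against 3 h with 0 probes each time, and the named probes hold the adjusted p alone, which cannot lose a call. The named probes were also picked as the largest changes in the same data. Their pairs include root minus shoot for Hv1045E17_1 at 3 h and for Hv3007F02_1 and Hv2050O22_1 at 6 h, whose root values were not measured. For these the kept calls show nothing on a tissue difference. Scaling between arrays, which makes all arrays equally spread, gave 4674 and 5353 probes in shoot at 3 h and 6 h, 3364 and 3517 in root, 133 for shoot at 6 h against 3 h, and 4554 and 4958 for root minus shoot at 3 h and 6 h. The adjusted p alone, a looser rule by construction, gave 25431, 26423, 6591, 5600, 5316, 19700 and 20592 in the same order, and 28602 for untreated root against shoot. Testing against a 2-fold change, a stricter rule, gave 4330, 6049, 332, 354, 21, 2062 and 3330. In root, the scanner's processed signals gave 2541 at 3 h and 2661 at 6 h and the values of the deposited series 2543 and 2677; the cause was not tested. The root arrays at 3 h fitted alone gave 953, with fewer degrees of freedom and with the spread of that group in place of the pooled one. Which of these lowered the count was not tested. The stricter filter gave 968 for shoot at 6 h against 3 h, over fewer probes. Root at 24 h had 1790 probes called in a fit of all 18 arrays that takes the lone array to vary like the others, against 3945 counted without a test, and 827 of the 1790 were up where 2303 of the 3945 were.

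Leaving out each replicate gave 8649 to 9223 in shoot at 3 h, 10105 to 10693 at 6 h, 1376 to 1679 in root at 3 h, 1112 to 1800 at 6 h, 900 to 1588 for shoot at 6 h against 3 h (982 without replicate 2 and 900 without replicate 3), 0 for root at 6 h against 3 h, 7067 to 7844 and 8539 to 8991 for root minus shoot, and 14480 to 15154 for the untreated tissues. With the replicate block the counts were 8951, 10421, 1668 and 1594 against untreated, 1742 and 0 for 6 h against 3 h in shoot and root, 8377 and 9512 for root minus shoot and 15124 for the untreated tissues. This block, which takes a replicate number as shared by both tissues, changed no count by over 1.5 times. Same-numbered arrays correlated more within a tissue (0.503 to 0.884) than across tissues (0.138 to 0.473), so the block does not take up all of the pairing. Root at 6 h against 3 h had 0 probes under every alternative run. Aquantile leaves ratios as they are and tests nothing for them. The gene list alternatives were not run, since no list had members. Signal over background limits the root values of probes that are bright only in shoot: 334 of the 9104 probes at 6 h had 1 tissue with neither channel well above background.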

Other observations

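The tests on root arrays at the end were chosen after the data were seen. The tests on amino acid motifs below were fixed after the files were seen but before any intensity was read. The 60-mers of 6 of the 42483 probes encode a listed motif in a forward frame, against 0 in the reverse frames, and 5 of them were among the probes tested. A motif is a property of the probe sequence and does not name a gene. Hv2121F15_1, with sequence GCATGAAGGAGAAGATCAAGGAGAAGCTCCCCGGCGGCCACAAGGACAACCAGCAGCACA, encodes the K-segment that marks dehydrins, proteins that accumulate in drying plant tissue. It rose in shoot by 4.48 (SE 0.37, limma adjusted p 9.54e-08) at 3 h and 4.21 (SE 0.37, limma adjusted p 1.37e-07) at 6 h, and in root by 2.48 (SE 0.37, limma adjusted p 0.000485) and 2.76 (SE 0.37, limma adjusted p 0.000218), with 4.10 and 2.70 on the arrays at 24 h. Hv3026O14_1, which encodes the EEVD tail of cytosolic chaperones, rose in shoot by 1.91 (SE 0.25, limma adjusted p 1.07e-05) at 3 h and 2.01 (SE 0.25, limma adjusted p 5.43e-06) at 6 h, and stood in root at 0.78 at 3 h and 1.16 at 6 h (SE 0.25, limma adjusted p 0.00688). Hv2060N05_1, with a cytochrome P450 haem loop, rose in shoot by 2.79 at 3 h and 3.62 at 6 h, and stood in root at 1.59 and 1.42 (SE 0.49; limma adjusted p 0.0373 and 0.0669 in root). Hv3087P11_1, with the tail of actin, stood at -0.79 at 3 h and -1.09 at 6 h in shoot and at 0.43 and 0.33 in root (SE 0.16), and -2.59 on the shoot array at 24 h. Hv2039N16_1, with the tail of lipoxygenases, stood at 0.57 at 3 h and 1.01 at 6 h in shoot (SE 0.37, limma adjusted p 0.0258 at 6 h), and at -0.19 and -0.24 in root. These 5 probes were not examined under other normalizations.

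The 842 probes that rose at least 8-fold in shoot at 6 h were followed on each root array. Their median log ratio in root at 3 h was 2.09, 0.98, 0.23 and 1.64 in replicates 1 to 4, and at 6 h it was 1.48, 1.13, 1.38 and 1.72. In shoot at 3 h the medians lay between 3.36 and 4.40. Root replicate 3 at 3 h had the lowest of these medians, and no explanation was tested.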
